A study of Homo sapiens with 3 samples.

How the data were processed

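MDA-MB-231 breast cancer cells were transfected with plasmids for Flag-tagged CASC3 or Flag-tagged MTDH, and RNA was recovered with an antibody against Flag, per the labels. The libraries were prepared with a stranded RNA-seq kit and sequenced on an Illumina instrument, per the labels. The groups were the CASC3 RIP, the MTDH RIP and the input, with 1 library each, taken from the sample titles. The labels' protocol mentions control mouse IgG, and no such pull-down was analysed here, so background binding to the beads has no measure of its own. The protocol also names antibodies against CASC3 and MTDH. The antibody field of both pull-downs reads anti-Flag and was followed, so whether untagged protein was pulled down as well is not settled by the labels. The labels do not state whether the input cells were transfected.

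Reads were aligned with HISAT2 to hg19, per the submitters' processing notes, without the version. The tool that turned alignments into expression values, the annotation and any filter are not given in the sources used here. The deposited files hold FPKM values per gene, per the file headers, fragments counted relative to transcript length and to the mapped total; the header of the input file spells the unit differently. All 12095 genes in each file are typed as protein-coding, and every gene reached 0.5 FPKM in at least 1 library. Genes low in all libraries are therefore absent from the values, and noncoding RNAs were not analysed here. Coordinates are those of the files, on hg19, and gene names are those of the files. In 5 cases a symbol occurred more than once; each entry was kept under its own identifier.

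FPKM values carry no read counts, so the depth and the counting error of each value are unknown. A search for whole reads in the FPKM of short histone genes gave values within 0.05 of a whole number for 40.0% of the genes in the CASC3 RIP, 33.3% in the MTDH RIP and 35.7% in the input, no more than the 40.0%, 40.0% and 35.7% of shifted values, so reads were not recovered. The summed FPKM differ between the libraries, so the split of genes into higher and lower depends on the scaling.

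Log2 ratios were computed as the log2 of (FPKM + 1) in one library over (FPKM + 1) in the other, a scale that understates the difference of low genes. Genes with a mean over the 3 libraries of at least 1 FPKM entered the comparisons, 10765 genes, and 1330 genes were left out. Genes at least 2-fold higher or lower were counted by size alone. For each gene list the median log2 ratio was placed as a percentile among 10000 random lists of the same size matched on mean expression in 20 bins, and lists outside percentiles 2.5 to 97.5 were noted. The percentile describes these libraries only. Before the data were examined, 30 gene lists with 672 entries were fixed, of which 574 entries were found, and 24 lists had at least 5 measured members. Lists of nuclear-retained long noncoding RNAs and of abundant structured RNAs had 0 members among the genes. Some lists written as background, such as that of reported nonsense-mediated decay substrates, share members with others.

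The named genes were set by a rule written before the data were examined. They are CASC3 and MTDH, the 10 highest and 10 lowest log2 ratios per comparison among the 6642 genes with a mean of at least 5 FPKM, leaving out symbols with listed prefixes of small RNAs and of some clone-based names, and for each list up to 2 members with the highest and up to 2 with the lowest log2 ratio. Clone-based names with other prefixes, such as AC239799.1 and AC106886.5, stayed in. ZBED6, which overlaps a named gene, and the further genes of the closing section fall outside this rule and were chosen after their values were seen. Some gene families are not reported here. The comparison by exon number was planned, and exon numbers, transcript lengths and base composition were not used here. The genomic span of each gene on hg19 stood in for them, and random lists matched on transcript length were not run.

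The correlation of the log2 ratios was set beside 100 simulations of unchanged libraries against 1 shared input. All 3 simulated libraries had equal noise (SD 0.97 on the log2 scale), set from the spread of the ratio between the pull-downs. Real differences between the pull-downs therefore counted as noise, and no shift of the median was simulated. The alternatives tried were pseudocounts of 0.1 and 5, no filter and a filter at 5 FPKM, ratios centred on their median, scaling by a trimmed mean of log ratios (30% of ratios and 5% of levels trimmed at each end, without weights), removal of mitochondrially encoded genes with rescaling, and random lists matched on the input level. Chosen after the data were seen were a filter on the mean of the 2 libraries compared, removal of genes listed at 0 and random lists matched on gene span. The procedure was tested on simulated data with known changes. The simulated noise was chosen by hand, since no replicate gives a noise level, and changed genes had a simulated mean of at least 5 FPKM. The shares below therefore do not measure recovery in these libraries. In each comparison 100% of simulated 4-fold, 8-fold and 16-fold genes passed 2-fold in the right direction. Of simulated 2-fold genes 42.0% did so for the CASC3 RIP against input, 22.0% for the MTDH RIP against input and 32.0% between the pull-downs, and of unchanged lists 5%, 6% and 4.5% lay outside the percentile range. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.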

Results

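RNA that came down with Flag-tagged CASC3 or MTDH was compared with input RNA in MDA-MB-231 cells, an established line of triple-negative breast cancer. CASC3 is a core member of the exon junction complex, which is placed on mRNA upstream of exon junctions during splicing. MTDH (metadherin) is a membrane-associated protein of the endoplasmic reticulum and the nucleus that is often raised in breast tumours. In RNA immunoprecipitation (RIP), an antibody recovers a protein together with the RNA bound to it. The data comprised 3 libraries, a CASC3 RIP, an MTDH RIP and an input, with 1 library per group, so no difference has a replicate check and no p-value is given. Each library held FPKM values for the same 12095 protein-coding genes. The summed FPKM was 126344 in the CASC3 RIP, 171669 in the MTDH RIP and 276762 in the input, and the depth in reads is unknown. The median gene was similar in all 3 libraries, at 4.36 FPKM in the CASC3 RIP, 4.15 FPKM in the MTDH RIP and 4.69 FPKM in the input. Mitochondrially encoded mRNAs took 31.7% of the summed FPKM in the input, against 5.58% in the CASC3 RIP and 8.62% in the MTDH RIP.

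The transcripts of the tagged proteins were examined first. CASC3 (chromosome 17, 38296571 to 38328436, hg19) was at 22.7 FPKM in the CASC3 RIP, 17.5 FPKM in the MTDH RIP and 7.95 FPKM in the input. MTDH (chromosome 8, 98656407 to 98740998) was at 22.0 FPKM in the CASC3 RIP, 28.2 FPKM in the MTDH RIP and 63.0 FPKM in the input. As log2 ratios of FPKM + 1, CASC3 was 0.36 higher in its own pull-down than in that of MTDH. MTDH stood at -0.35 in the same comparison, so it was also slightly higher in its own pull-down (0.03 without the mitochondrially encoded genes), but at -1.13 against input. Neither transcript was 2-fold higher in its own pull-down than in the other, and plasmid-derived and endogenous mRNA cannot be separated in these values, so they do not check the labels.

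The CASC3 RIP was compared with input to find which mRNAs came down with CASC3. Replication-dependent histone mRNAs and mRNAs of giant proteins were the highest groups, and mitochondrially encoded mRNAs were the lowest. Of 17 histone genes, 16 were at least 2-fold higher than in input, with a median log2 ratio of 2.82. The linker histone gene HIST1H1E was at 342 FPKM against 1.66 FPKM, and HIST1H3B was at 77.3 FPKM against 0.588 FPKM, while HIST1H2AC was lower (log2 ratio -1.13). Of 17 genes of giant proteins, 15 were at least 2-fold higher, with a median of 4.65; MDN1, a ribosome assembly factor (5.27), and DST, a cytoskeletal linker (5.26), led the group, and AHNAK (-1.70) was the member at least 2-fold lower. All 13 mitochondrially encoded mRNAs were at least 2-fold lower, with a median of -3.70, from -2.99 for MT-ND4L to -4.39 for MT-ATP6.

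mRNAs of nonsense-mediated decay factors, which degrade transcripts with premature stop codons, were also higher in the CASC3 RIP, at a median of 1.24. In this group 10 of 17 genes were at least 2-fold higher, among them SMG1, the kinase of UPF1 (104 FPKM against 2.31 FPKM), and NBAS (log2 ratio 4.11). The decapping adaptor gene PNRC2 was the member at least 2-fold lower, at 0.411 FPKM against 28.1 FPKM. Receptors, integrins and transporters had a median of 0.60, with LRP1 (3.57) and NOTCH2 (2.96) highest and CD44 (-2.49) and ATP1B1 (-1.88) lowest. The list of exon junction complex genes covers the core of the complex and its periphery, so not every member is a subunit. Of these genes, 10 of 15 were at least 2-fold lower (median -1.62), including MAGOH (-2.92), a core subunit, and SAP18 (-3.48). At least 2-fold higher were 3, among them ACIN1 (1.89) and NXF1 (1.88). All 23 measured intronless genes were at least 2-fold lower, with a median of -2.13, FOXQ1 (-2.98) and CEBPB (-2.94) lowest.

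Ribosomal protein, oxidative phosphorylation, proteasome and translocon genes had negative medians in the CASC3 RIP against input, below the range matched on mean expression but not below that matched on the input level. Of 77 cytosolic ribosomal protein genes, 74 were at least 2-fold lower (median -2.36), with RPL34 (-3.63) and RPS7 (-3.39) lowest and RPLP0 (0.17) highest. Mitochondrial ribosomal proteins had a median of -2.11, with MRPL19 (-3.48) lowest, and nuclear-encoded oxidative phosphorylation a median of -2.29, with COX6C (-3.71) and NDUFA2 (-3.69) lowest. The proteasome median was -2.05, with PSMD8 (-3.27) and PSMB3 (-3.27) lowest. Translocon and signal peptide genes also had a median of -2.05, with SRP14 (-4.25) and SRP9 (-3.99), the small subunits of the signal recognition particle, lowest.

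Among single genes in the CASC3 RIP, the highest log2 ratio to input after HIST1H1E (7.01) was that of ZC3H11A, which encodes a zinc finger protein of mRNA export, at 172 FPKM against 1.06 FPKM; its locus overlaps that of ZBED6, so how reads were divided between them is uncertain. BIRC6, a giant inhibitor of apoptosis, was also among the 10 highest, at 225 FPKM against 2.79 FPKM. The histone genes HIST1H3C (5.97) and HIST1H2AH (5.87) belonged to them as well, together with NBPF20 (6.18), NBPF14 (6.00), NBPF10 (5.86), NBPF8 (5.73) and AC239799.1 (6.01). The NBPF genes are near-identical copies and the locus of AC239799.1 overlaps that of NBPF10, so how reads were divided among them is uncertain. The lowest gene was TOMM6, a small subunit of the mitochondrial outer membrane translocase, at 2.05 FPKM against 392 FPKM. EID1 (-4.62), DNAJC25-GNG10 (-4.45), SPANXD (-4.42), PNRC2 (-4.36), CENPW (-4.35) and SRP14 (-4.25) followed, and SPANXC and INO80B-WBP1 were listed at 0 in the CASC3 RIP, at 21.5 FPKM and 18.9 FPKM in the input. The SPANX genes and the readthrough models share sequence with neighbouring or related genes.

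Over 10765 genes, 2432 were at least 2-fold higher and 3600 at least 2-fold lower in the CASC3 RIP than in input, so 40.3% of the genes that differed by 2-fold were higher. That share was 51.4% with ratios centred on their median, which sets it near even largely by construction. It was 52.3% with trimmed mean scaling. After the mitochondrially encoded genes were removed and the values rescaled it was 59.9%, and the median of all genes moved from -0.32 to 0.22. Against 10000 random lists matched on mean expression, 4 of 24 gene lists lay above the matched range and 8 below it. The 4 above were the giant proteins (percentile 100), histones (100), receptors and transporters (99.6; 95.4 when matched on gene span) and nonsense-mediated decay factors (99.5). With random lists matched on the input level instead, the intronless genes (0.01) and the mitochondrially encoded mRNAs (0) were still below, and the exon junction complex (14.8), cytosolic ribosomal proteins (97.4), mitochondrial ribosomal proteins (3.12), oxidative phosphorylation (7.07), the translocon group (18.3) and the proteasome (33.8) were not.

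**Figure D1:**
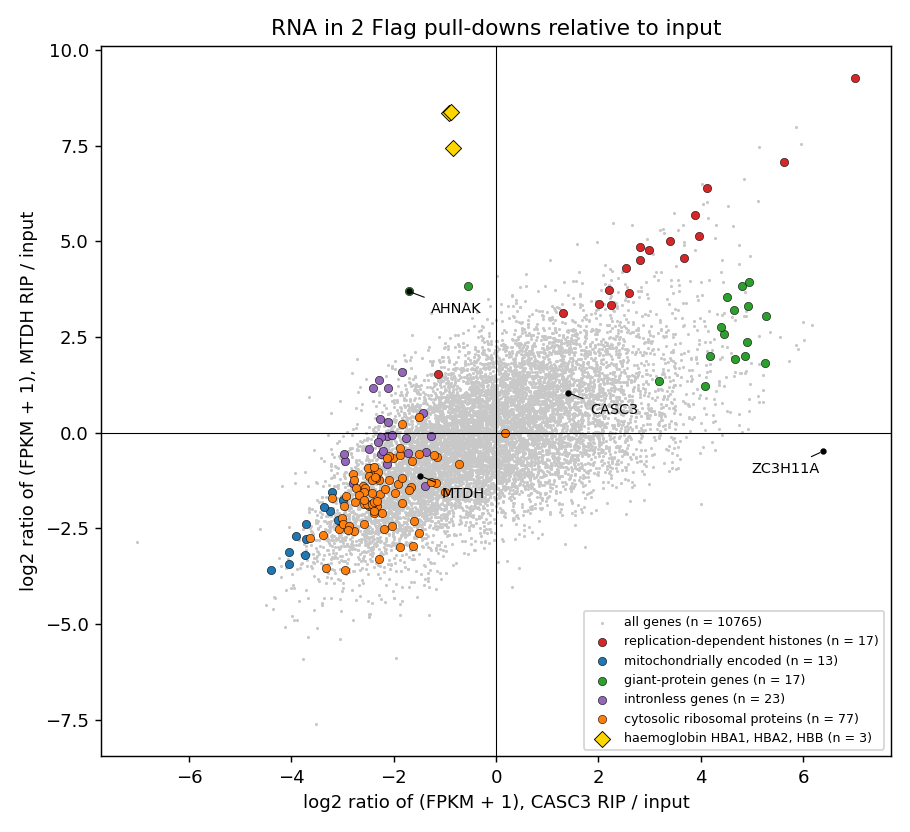
Log2 ratio of FPKM + 1 to input for 10765 genes, with the CASC3 RIP on the horizontal axis and the MTDH RIP on the vertical axis; each point is a gene and colours mark gene lists. The haemoglobin genes stand apart at 7.45 to 8.38 in the MTDH RIP, and the 13 mitochondrially encoded genes lie below 0 on both axes.

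The remaining lists lay inside the matched range for the CASC3 RIP against input. Those with negative medians were endoplasmic reticulum chaperones (-1.89, PPIB -3.07 lowest and UGGT1 4.03 highest), glycolytic enzymes (-1.54), cytosolic chaperones (-1.52), cytoskeleton and motility (-1.41), luminal breast epithelium markers (-1.32), mesenchymal and invasion genes (-1.05) and interferon-stimulated genes (-0.92). Within the mesenchymal list ZEB1 was at 60.8 FPKM against 1.72 FPKM, and S100A4 at 14.2 FPKM against 160 FPKM. Secreted and matrix proteins had a median of -0.52, which became 0.09 without the mitochondrially encoded genes; LAMA5 (4.75) and HSPG2 (4.41), both basement membrane proteins, were highest. Medians nearer 0 belonged to SR splicing factors (-0.01), cell cycle genes (-0.14), reported nonsense-mediated decay substrates (-0.20) and NF-kappaB targets (0.22), and the first 3 of these were positive under every other scaling tried. Other matching moved 7 of these lists outside the range. On the input level, cell cycle genes (99.95), cytosolic chaperones (99.8) and SR factors (99.4) were above it. On gene span, endoplasmic reticulum chaperones (0.05), glycolytic enzymes (0.775), cytoskeleton and motility (0.795) and cytosolic chaperones (1.52) were below it and NF-kappaB targets (99.0) above it.

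The MTDH RIP was compared with input in the same way. Among lists with at least 5 measured members, histone mRNAs were the highest group. Secreted proteins, giant proteins and the list of receptors, integrins and transporters were higher as well. Broader families of membrane proteins, grouped by symbol prefix after the result was seen, were not. The 148 TMEM genes had a median of -0.93 and the 179 SLC genes a median of -0.14. All 17 histone genes were at least 2-fold higher, with a median of 4.56, and HIST1H1E reached 1639 FPKM. Of 30 secreted and matrix protein genes, 19 were at least 2-fold higher (median 1.57), among them AGRN (164 FPKM against 3.94 FPKM) and HSPG2 (66.4 FPKM against 1.96 FPKM), while the cytokine genes CXCL8 (-2.88) and IL6, listed at 0 in the MTDH RIP, were lower. Of 29 receptors, integrins and transporters, 18 were at least 2-fold higher (median 1.37), led by ITGB4, an epithelial integrin (532 FPKM against 31.1 FPKM), and IGF2R (3.86). All 17 giant protein genes were at least 2-fold higher (median 2.76), with KMT2D (3.94) and AHNAK2 (3.84) highest.

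The adult haemoglobin genes stood far above their input level in the MTDH RIP. HBA1 (chromosome 16, 226679 to 227521) was at 991 FPKM in the MTDH RIP, 0.605 FPKM in the CASC3 RIP and 2.02 FPKM in the input. HBB (chromosome 11, 5246694 to 5250625) was at 786 FPKM, 0.286 FPKM and 1.36 FPKM in the same order, and HBA2, a near-identical copy of HBA1, at 412 FPKM, 0.316 FPKM and 1.37 FPKM. Tested markers of other cell types were likewise higher in this library, though at far lower levels. Those tested were 3 of 6 hepatocyte and neuronal, 4 of 6 immune and blood and 3 of 4 fibroblast genes in the files. Some, such as APOB and LYZ, passed the filter on the mean over the 3 libraries only through this library, which favours this direction. Several, such as ALB and COL1A1, encode secreted proteins, and the list of secreted and matrix proteins was higher in this library as well (median 1.57). The direction of these markers therefore does not point to other cells by itself. The liver genes ALB, SERPINA1 and APOB were at 5.85, 5.27 and 2.69 FPKM in the MTDH RIP and at 1.93, 1.28 and 0.148 FPKM in the input. Of the immune cell list, LYZ was at 3.15 FPKM against 0.277 FPKM and CD68 at 34.7 FPKM against 8.94 FPKM, and of the fibroblast list, PDGFRB was at 6.63 FPKM against 1.12 FPKM and COL1A1 at 3.60 FPKM against 0.354 FPKM.

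Mitochondrially encoded, cytosolic ribosomal protein, oxidative phosphorylation, translocon and proteasome mRNAs had negative medians in the MTDH RIP against input, below the range matched on mean expression but not below that matched on the input level. The 13 mitochondrially encoded mRNAs had a median of -2.39 and were all at least 2-fold lower. Medians were -1.58 for cytosolic ribosomal proteins (61 of 77 at least 2-fold lower), -1.71 for oxidative phosphorylation (20 of 30), -1.60 for the translocon group (18 of 26) and -1.35 for the proteasome (17 of 28). Within these groups SRP9 (-4.78), SEC62 (-3.44), RPS29 (-3.58) and NDUFA4 (-3.56) were among the lowest, whereas PSMD2 (2.53) and SDHA (2.25) were higher. SR splicing factors, with 10 of 13 at least 2-fold lower, had a median of -1.39, with SRSF6 (-2.23) and TRA2A (-2.10) lowest, and exon junction complex genes a median of -1.42, with MAGOH at -3.41 and UPF3B listed at 0.

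Besides HIST1H1E (9.27) and the haemoglobin genes, the 10 highest single genes in the MTDH RIP were histone genes: HIST1H2AH (7.99), HIST1H3C (7.54), HIST1H2AI (7.47), HIST1H3B (7.07) and HIST2H3D (6.64), and HIST2H2AB, which was at 89.7 FPKM and listed at 0 in the input. Of the 10 lowest genes, 8 were listed at 0 in the MTDH RIP: NME1-NME2, MZT1, UBE2T, TMEM14A, RIDA, TMEM35B, RPL17-C18orf32 and CCDC167. Their input values ran from 28.5 FPKM for CCDC167 to 195 FPKM for NME1-NME2, a readthrough model. Such zeros can be failed estimates, since 556 genes were listed at 0 in this library. POLR2K, a shared subunit of the RNA polymerases, was at 1.84 FPKM against 97.0 FPKM, and NDUFAF2, an assembly factor of respiratory complex I, at 2.48 FPKM against 102 FPKM.

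In the MTDH RIP 2271 genes were at least 2-fold higher and 3239 at least 2-fold lower than in input, so 41.2% were higher. With ratios centred on their median, which sets it near even largely by construction, this share was 50.3%. With trimmed mean scaling it was 46.8% and without the mitochondrially encoded genes 50.2%. Of 24 lists, 4 lay above the matched range, namely histones, giant proteins, secreted proteins and receptors and transporters, and 7 below it. When random lists were matched on the input level, none of the 7 stayed below: mitochondrially encoded mRNAs (4.56), oxidative phosphorylation (9.64), exon junction complex (10.9), translocon group (13.8), SR factors (15.7), proteasome (52.1) and cytosolic ribosomal proteins (70.3). Inside the range were mitochondrial ribosomal proteins (-0.95), interferon-stimulated genes (-0.43), cytosolic chaperones (-0.40), nonsense-mediated decay factors (0.09), cell cycle genes (0.12), cytoskeleton and motility (0.12), NF-kappaB targets (0.13), luminal markers (0.17), reported nonsense-mediated decay substrates (0.27), mesenchymal genes (0.30) and glycolytic enzymes (0.44). Intronless genes (-0.14) and endoplasmic reticulum chaperones (-0.03) were inside it too, with medians that turned positive under the other scalings. Of the lists inside the range, glycolytic enzymes (100), cytoskeleton and motility (99.99), endoplasmic reticulum chaperones (99.9), cytosolic chaperones (99.9) and cell cycle genes (99.7) lay above it when matched on the input level. Matched on gene span, the SR factors (2.71) were the only list of the 7 no longer below.

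**Figure D2:**
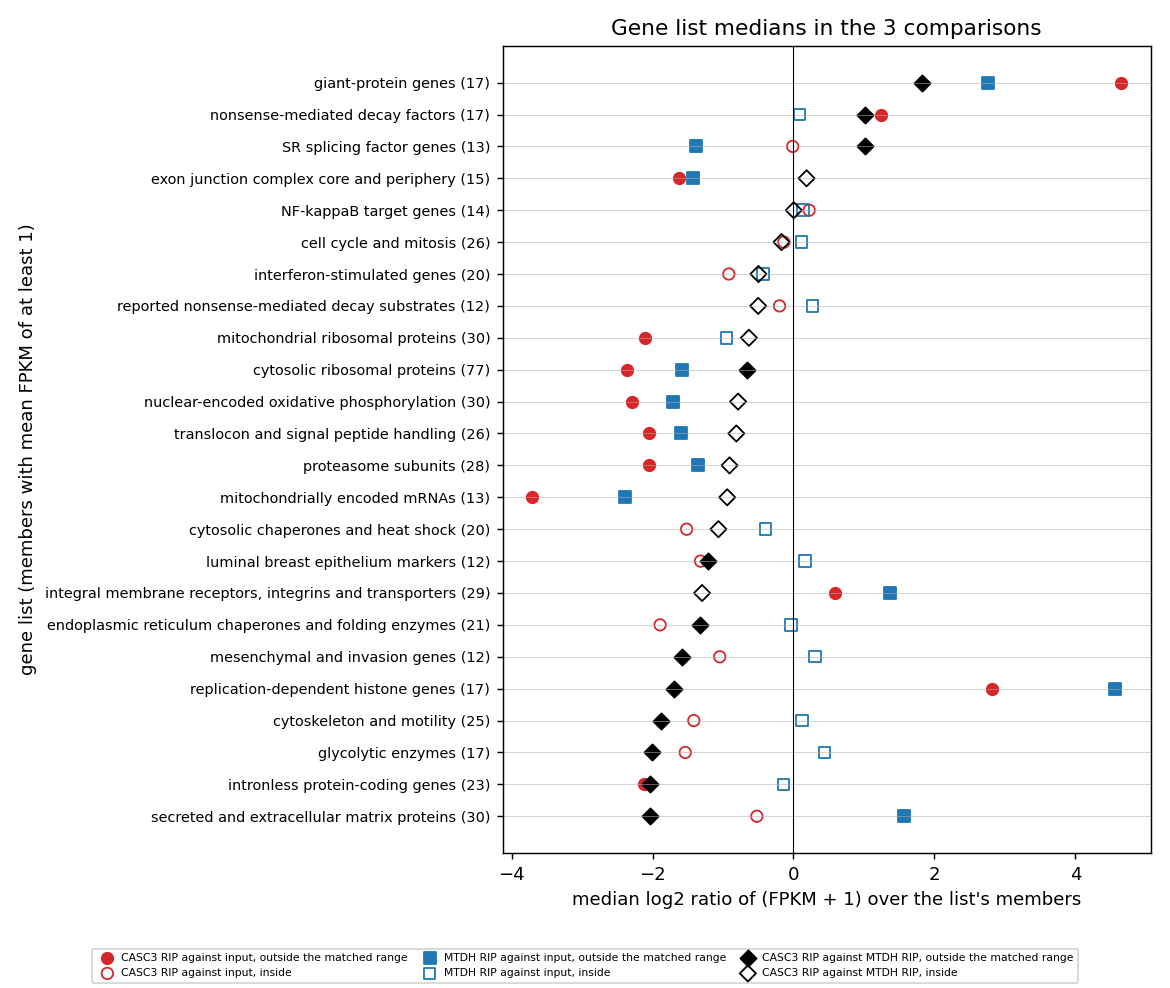
Median log2 ratio of FPKM + 1 for 24 gene lists in the 3 comparisons, with the number of measured members in brackets; filled symbols lie outside the central range of random lists matched on mean expression. Giant proteins are highest in the CASC3 RIP (4.65), and intronless genes are at -2.03 in the CASC3 RIP against the MTDH RIP.

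The 2 pull-downs were compared directly to separate what came down with CASC3 from what came down with MTDH. Intronless genes, secreted proteins, glycolytic enzymes and cytoskeletal genes were lower in the CASC3 RIP, while giant proteins, nonsense-mediated decay factors and SR splicing factors were higher. Of 23 intronless genes, 21 were at least 2-fold lower (median -2.03), among them JUN, an immediate early transcription factor (3.48 FPKM against 55.8 FPKM), and HSPA1B, an inducible heat shock gene (3.92 FPKM against 56.8 FPKM). All 17 glycolytic enzyme genes were at least 2-fold lower (median -2.0), with TPI1 (-2.90) and ALDOA (-2.64) lowest and HK2 (-1.25) and ENO2 (-1.19) highest. Of 30 secreted and matrix genes, 21 were at least 2-fold lower (median -2.03), with LAMB3 (27.0 FPKM against 443 FPKM) and CTSB (2.68 FPKM against 49.1 FPKM) lowest. Cytoskeleton and motility genes had a median of -1.89, with VIM, the mesenchymal intermediate filament, at 34.4 FPKM against 474 FPKM.

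Histones (-1.70), mesenchymal and invasion genes (-1.58), endoplasmic reticulum chaperones (-1.32) and luminal breast epithelium markers (-1.21) were also lower in the CASC3 RIP than in the MTDH RIP. Examples were MMP14, a membrane metalloprotease (-3.23), PDIA3 and P4HB, protein disulphide isomerases (-3.25 and -2.85), and the keratins KRT19 (-2.92) and KRT8 (-2.65), while ZEB1 (3.94) was higher. Nonsense-mediated decay factors had a median of 1.02, with XRN1, the cytoplasmic exonuclease (20.8 FPKM against 1.36 FPKM), and SMG1 (3.15) highest, and UPF1 (-1.33) and SMG5 (-1.12) lowest. SR splicing factors had a median of 1.01, with 7 of 13 genes at least 2-fold higher, SRSF6 (2.56) and TRA2A (2.28) leading. Giant protein genes had a median of 1.82, with 12 of 17 at least 2-fold higher, led by DST (3.43) and VPS13C (2.88).

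Single genes highest in the CASC3 RIP over the MTDH RIP were ZC3H11A (6.88), BRWD3 (4.82), the ciliary dynein gene DYNC2H1 (4.78), ATAD5 (4.72), the mitotic kinesin gene KIF20B (4.72), CCDC18 (4.66), the centrosomal gene CEP290 (4.65), NF1 (4.55), AC106886.5 (4.53) and NPIPA5, listed at 0 in the MTDH RIP and at 57.3 FPKM in the CASC3 RIP. NPIPA5 belongs to a near-identical family. Lowest were HBA1 (-9.27), HBB (-9.26) and HBA2 (-8.30), followed by AHNAK, at 3.66 FPKM against 195 FPKM, and its relative AHNAK2 (-4.38), giant proteins encoded mostly by a large exon. FEN1, a flap endonuclease (-4.64), LASP1 (-4.57), MOGS, the glucosidase that starts glycan trimming (-4.40), CAVIN1, a caveolar coat protein (-4.39), and TOR4A (-4.19) completed the 10 lowest.

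Between the pull-downs, 2313 genes were at least 2-fold higher and 2549 at least 2-fold lower in the CASC3 RIP. The share that was higher was 47.6%, against 58.1% with trimmed mean scaling and 63.9% without the mitochondrially encoded genes, and the median of all genes moved from -0.10 to 0.12 and 0.22. Of 24 lists, 4 lay above the matched range and 8 below it. The cytosolic ribosomal proteins were among the 4 above (99.7) although their median was -0.66, since random lists of such abundant genes had a median of -1.06, and they were inside the range when matched on input (96.5) or on gene span (58.8). Receptors and transporters (median -1.30, 18 of 29 at least 2-fold lower) were inside the range at percentile 2.87, and below it when matched on the input level (0.03) or on gene span (0). Inside the range lay also cytosolic chaperones (-1.06), mitochondrially encoded mRNAs (-0.94), the proteasome (-0.91), the translocon group (-0.81), oxidative phosphorylation (-0.79), mitochondrial ribosomal proteins (-0.63), reported nonsense-mediated decay substrates (-0.50), interferon-stimulated genes (-0.50), NF-kappaB targets (0.00) and exon junction complex genes (0.19). Cell cycle genes were inside it at -0.17, positive with trimmed mean scaling and without the mitochondrially encoded genes. Matched on gene span, cytosolic chaperones (1.23) and the proteasome (1.77) were below it.

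Some lists had too few measured members for a percentile. The 2 measured small nucleolar RNA host genes differed between the pull-downs, NCL, the nucleolin gene, being at 67.6 FPKM in the CASC3 RIP and 385 FPKM in the MTDH RIP, and NOP56, a ribonucleoprotein core gene, at 128 FPKM and 27.8 FPKM. The median log2 ratio of the CASC3 RIP to the MTDH RIP was -6.10 over 4 immune and blood markers (HBA1 -9.27, HBB -9.26, CD68 -2.93 and LYZ -1.61). It was -2.05 over 3 hepatocyte and neuronal markers and -1.22 over 3 fibroblast markers. Some of these markers, such as APOB and LYZ, passed the filter on the mean only through the MTDH RIP.

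The pull-downs were also set side by side through their ratios to input. Across 10765 genes, which are not independent replicates, the log2 ratios of the CASC3 RIP and of the MTDH RIP had a Pearson correlation of 0.63 and a Spearman correlation of 0.61. Both ratios share the input library, and unchanged groups simulated against a shared input had a correlation of 0.50 and a covariance of 0.95, against an observed covariance of 1.58. At least 2-fold higher in both were 1155 genes, where independent lists would share 513 and the simulation 1171, and at least 2-fold lower in both were 2195, against 1083 and 1171. Equal noise in the simulated libraries fixes their correlation near 0.50, so that value is no measure of these libraries. The simulation had no shift of the median, whereas the observed medians were -0.32 and -0.21, so its overlaps are not a like comparison. The input cannot be split and its own noise is unknown, so part or all of the excess may come from it. Opposite directions were rarer than the same direction, which a shared input itself favours. They were seen for 133 genes higher with CASC3 and lower with MTDH, and for 118 genes the other way.

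Genes were finally grouped by genomic span, because CASC3 sits at exon junctions and long genes have more of them. Short genes were lower and long genes higher in the CASC3 RIP. From the quartile of shortest genes (median span 6.84 kb) to that of the longest (134 kb), the median log2 ratio to input ran through -1.21, -0.58, -0.06 and 0.77. In the MTDH RIP the same medians were -0.41, -0.24, -0.32 and 0.11. The Spearman correlation of span with the log2 ratio across genes was 0.45 for the CASC3 RIP against input, 0.15 for the MTDH RIP against input and 0.37 for the CASC3 RIP against the MTDH RIP. Span includes introns and stands in for exon number, which was not used here.

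**Figure D3:**
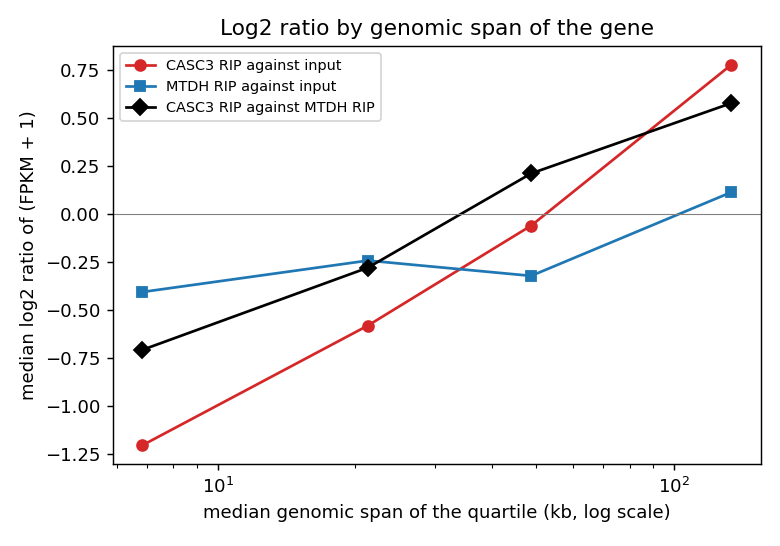
Median log2 ratio of FPKM + 1 by quartile of genomic span, placed at the median span of each quartile in kb on a log axis, for the 3 comparisons. The CASC3 RIP against input runs from -1.21 in the shortest quartile to 0.77 in the longest.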

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

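Genes that moved in opposite directions against the shared input in the 2 pull-downs were looked for after the comparisons had been made, and the difference between the pull-downs was not tested, since each group has 1 library. At least 2-fold higher with CASC3 and at least 2-fold lower with MTDH were 133 genes, and 118 genes were the other way round. These are few beside the 1155 genes higher in both and the 2195 lower in both.

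Among the named genes, AHNAK had a log2 ratio of the CASC3 RIP to the MTDH RIP of -5.40, being below input with CASC3 and above it with MTDH. FEN1 (-4.64), MOGS (-4.40), CAVIN1 (-4.39) and TOR4A (-4.19) had the same pair of directions. The opposite pair was found for KIF20B (4.72), CCDC18 (4.66), CEP290 (4.65) and NPIPA5 (5.87), the last listed at 0 in the MTDH RIP and a member of a near-identical family. CEP290 was at 52.2 FPKM with CASC3, 1.12 FPKM with MTDH and 6.16 FPKM in the input, and FEN1 at 6.07 FPKM, 176 FPKM and 45.6 FPKM.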

How the results depend on the processing

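No paired analysis was possible because each group has 1 library, and for the same reason no library could be left out; the unknown depth limits the low genes most. The 3 alternatives chosen after the data were seen were the filter on the mean of the 2 libraries compared, the removal of genes listed at 0 and matching on gene span. Matching on transcript length was not run. No list median outside the matched range and no named gene at least 2-fold apart turned its direction under any alternative. For the named genes this outcome was close to fixed in advance and is no sign of robustness. Pseudocounts and filters cannot turn the direction of a single gene, and the scalings tried moved the median of all genes by less than 2-fold. The balance of higher and lower genes did turn under other scalings: without mitochondrially encoded genes, 3507 were higher and 2343 lower in the CASC3 RIP than in input, 2680 and 2657 in the MTDH RIP, and 3125 and 1765 between the pull-downs. Of the values that answer a comparison, 134 stayed within 1.5 times a main count or inside the interval of a correlation and 22 did not, and of the list medians 599 stayed inside their interval and 46 moved; the cause was not tested except where stated. Single genes have no spread here. Of 2658 alternative values of named genes at least 2-fold apart, 84 were under 2-fold, and of 586 values of other named genes 31 had the opposite sign, among them MTDH between the pull-downs (0.03). The filters leave the ratio of a gene unchanged, so they add to the totals of 2658 and 586 but not to the 84 or the 31. With a pseudocount of 5, which shrinks every ratio by construction, genes at least 2-fold higher and lower were 1456 and 2302 for the CASC3 RIP against input, 1239 and 1914 for the MTDH RIP against input, and 1189 and 1402 between the pull-downs. With the filter at 5 FPKM, which tests fewer genes, 1461 were higher between the pull-downs. Matched on the input level, 7 lists lay above and 2 below for CASC3, and 9 above and 0 below for MTDH. The correlation of the ratios was 0.596 and 0.647 with pseudocounts of 0.1 and 5, 0.652 with the filter at 5 FPKM, 0.608 without mitochondrially encoded genes and 0.649 with the filter on the mean of 2 libraries. The span correlations were 0.422 (CASC3 against input) and 0.132 (MTDH against input) without a filter, and 0.495, 0.197 and 0.400 (between the pull-downs) with the filter at 5 FPKM.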

Other observations

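The gene families, the tests of histone binding by the tagged proteins, of liver cells and of organs other than liver in the MTDH RIP, of gene span, of gene density in the ratio to input and of the fixed intronless list were chosen only after the result was seen, as was the rule for mixed organ counts; the other tests were set before theirs. Among 49 families of at least 20 measured genes that share a symbol prefix, those of the centrosome, the deubiquitinases and the kinesins were among the high ones in the CASC3 RIP. Of 34 CEP genes, which encode centrosomal proteins, 21 were at least 2-fold higher than in input (median log2 ratio 1.54, percentile 100) and 21 were at least 2-fold higher than in the MTDH RIP (median 1.55). Of 42 USP deubiquitinase genes 25 were at least 2-fold higher than in input (median 1.38). The kinesin genes (KIF, 28 genes) had medians of 1.36 in the CASC3 RIP and 0.13 in the MTDH RIP against input.

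Other families were lower than input in both pull-downs. Genes with the prefix COX, that of cytochrome c oxidase (21 genes), had medians of -3.03 in the CASC3 RIP and -2.38 in the MTDH RIP against input. Those with the prefix ARL, that of a group of small GTPases (20 genes), had medians of -1.75 and -1.36. Genes with the prefix UBE (38 genes) had medians of -1.36 and -1.23, and 148 TMEM genes, which encode membrane proteins, of -1.17 and -0.93. All families were grouped by symbol prefix alone, so each can hold genes of other functions. They were not matched on gene span, with which the ratios to input themselves correlate.

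Histone mRNAs were higher than input in both pull-downs, and 3 explanations were weighed. Short genes reading too high is argued against by 14 other nuclear genes with a span under 1000 nt. Their median log2 ratio was -1.66 in the MTDH RIP and -1.90 in the CASC3 RIP. At least 2-fold higher in the MTDH RIP were 4 of them, including the haemoglobin genes HBA1 (8.36) and HBA2 (7.45). The upper quartile of the 14 genes (0.84) still lay far below the histone median (4.56). An input library with less RNA lacking a poly(A) tail remains a candidate explanation: 10 histone variant genes with polyadenylated mRNAs had medians of -1.07 in the MTDH RIP and -2.74 in the CASC3 RIP, and 0 of them were at least 2-fold higher in either. Binding of histone mRNA by the tagged proteins stays open, since the difference between the pull-downs (-1.70) does not bear on binding in both and no mock pull-down was analysed.

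Haemoglobin mRNAs were high in the MTDH RIP alone. The values go against liver cells as their source, though that test and its bound were chosen only after the result was seen. The lowest haemoglobin gene was at 66.9 times the highest of 13 liver genes (APOA2, 6.17 FPKM). All 10 further liver genes nonetheless reached 0.5 FPKM in the MTDH RIP, against 2 in the CASC3 RIP and 1 in the input. RNA of several tissues stays undecided: of 40 genes of 6 organs, a test set before, 15 reached 0.5 FPKM in the MTDH RIP, 4 in the CASC3 RIP and 6 in the input, which met its bound of 2 times, but the 30 that are not liver genes, required to meet it too only after the counts were seen, gave 5, 2 and 5, all 5 higher than in the CASC3 RIP and 2 higher than in the input. Red blood cell RNA is undecided. Only 6 of 21 further red cell genes were among the genes in the files. Every gene in the files reached 0.5 FPKM in at least 1 library, so the absent ones may have been under it in the MTDH RIP too. That would count against red blood cell RNA, but the filter behind the files is not given. All 6 were higher than in the CASC3 RIP (median log2 ratio 0.74), whereas 3 were lower than in input. These were SLC25A37 at 10.2 against 11.3 FPKM, SELENBP1 at 3.87 against 4.41 FPKM and BPGM at 1.46 against 7.29 FPKM. Binding of the cells' own haemoglobin mRNA by MTDH cannot be told apart from red blood cell RNA without a mock pull-down, although the lowest haemoglobin ratio lay 1.51 above that of the next gene that is not a histone, CEMIP (5.93).

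Long genes were higher and short genes lower in the CASC3 RIP. Span as the whole cause of the gene list differences is argued against, since 11 of the 12 lists outside the range against input stayed outside on the same side when random lists were matched on span, which does not bear on the span trend itself. Base composition may contribute to the difference between the pull-downs. The ratio of the CASC3 RIP to the MTDH RIP had a Spearman correlation of -0.32 with the number of listed genes within 500 kb, a stand-in for it. Within span quartiles the correlation was -0.27 to -0.11. Against input it was -0.0394 for the CASC3 RIP, so little trend with gene density was seen there, and 0.24 for the MTDH RIP. Base composition stays open for the ratio to input, since it was not measured and no values within span quartiles were computed. RNA held by CASC3 at exon junctions may contribute too. Between the pull-downs, 25 further genes with 1 or 2 coding exons had a median of -1.51, at percentile 0 of lists matched on gene density. All 25 were lower and 19 at least 2-fold lower, for example FZD2 (-3.03) and SOCS3 (-1.92). Their medians against input were -1.53 for the CASC3 RIP and 0.54 for the MTDH RIP, so part of the difference lies in the MTDH RIP. No matched percentile was computed for their ratio to input. In the CASC3 RIP against input, all genes of the shortest span quartile had a median of -1.21. The fixed lists leave the part of exon junctions undecided. Intronless genes were lower than in the MTDH RIP (-2.03) and than in input (-2.13). Histone genes, also without introns, were lower than in the MTDH RIP (-1.70) and higher than in input (2.82).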
